A study of Mus musculus with 40 samples.

How the data were processed

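RNA from mouse lung was measured on 40 one-colour Affymetrix arrays, in 8 groups of 5. Per the labels, the groups cross 2 strains (AJ and C3H), 2 treatments given by aspiration (an allergen in phosphate-buffered saline, or the saline alone, PBS) and 2 times after aspiration (6 h and 24 h). The labels leave a pair of points open. Titles abbreviate the allergen as OVA while descriptions give HDM, so the treatment is called allergen here. All 40 descriptions name the AJ strain although 20 titles carry C3H, so strain was taken from the titles. The labels give a number to each array of a group and do not say that each number is a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

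The deposited table holds 1 intensity per probe set and array on a linear scale, as the authors made it. Which software made these values was not given in the sources used here. In the deposited intensity values, the mean left after trimming 2 percent of probe sets at each end lay between 150.036 and 150.046 on every array, so the authors had scaled the arrays to a common trimmed mean. Array medians ran from 63.7 to 81.3, which means that the distributions had not been made equal. No value was at or below 0, and no detection calls were used here. The number of arrays limits the precision of every comparison. No pair of arrays held identical values, and correlations between arrays across probe sets ran from 0.875 to 0.985.

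Of 22690 probe sets, 64 were controls. Gene symbols came from the platform annotation: 20380 probe sets had 1 symbol, 691 had several and 1555 had none. Entrez numbers were found for 20351 probe sets in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols needed an update. Probe sets with several symbols or none were left out of the gene tests. A gene was represented by its brightest probe set over all arrays, a choice that mattered for some of the 4956 genes with more than 1 probe set. This left 12393 genes.

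Values were taken as log2(intensity + 16). The pseudocount of 16 understates the fold change of dim genes, and 13.6% of the values tested lay below it. A linear model with 8 group means was fitted to all 40 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 32 residual and 4.62 prior degrees of freedom). Each of 12 contrasts was adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05, two-sided. The contrasts were allergen against PBS in each strain at each time, the difference of that effect between strains (C3H minus AJ) at each time and between times (24 h minus 6 h) in each strain, and, among PBS mice, C3H against AJ and 24 h against 6 h. A gene is said to have risen, fallen or changed where it passed this threshold. Errors of fold changes are limma standard errors (SE), and errors of levels are standard deviations (SD).

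Before the data were examined, 27 gene lists, the tests, the rule for named genes and most alternatives were fixed. The lists were chemokines, type 2 response and alternative macrophage activation, mucus and goblet cell, acute phase and innate inflammation, interferon response, complement, cell cycle, extracellular matrix, glucocorticoid and stress response, circadian clock, oxidative stress and detoxification, MHC class II presentation, innate sensors, neutrophil, eosinophil, mast cell and basophil, macrophage with monocyte and dendritic cell, T and NK cell, B and plasma cell, alveolar epithelium, club cell, ciliated cell, smooth muscle, cardiac and skeletal muscle, endothelium, erythroid and adipose. Some genes stand in more than 1 list. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. For each allergen contrast the rule named the 12 largest rises and 8 largest falls among genes that passed and whose groups did not overlap. In other contrasts it named the 6 largest of each sign, and everywhere the 4 largest passing members of each list. Il4, Il5, Il13, Ccl11, Muc5ac, Clca1, Hc and Tlr4 were named in any case, and not every gene so named is printed.

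The test was checked on simulated data, drawn as independent normal noise with the residual SD of each gene around its mean. Of 12393 genes, 200 were changed, and the chemokine list was shifted by 0.5 in addition. Correlation between genes was left out, so the shares of false calls are those for genes that vary independently. For allergen against PBS in AJ at 24 h, 39.1% of changes of 0.5 and 91% of changes of 1 on the log2 scale were recovered, with 5.43% of calls false. For the difference between strains at 24 h, recovery was 11.7% and 69.5%, and for the difference between times in AJ it was 12.2% and 67.8%. In 90 simulated comparisons with no change, at most 2 genes were called. The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, leaving out the 25% of genes with the lowest mean, averaging all probe sets of a gene, trend and robust options, array weights, a replicate block, leaving out the 2 arrays with a letter b in their titles, fitting the compared groups alone, stricter thresholds, list tests on ranks, and leaving out each array in turn. Covariates for muscle and adipose transcripts and for the Gapdh 3 prime over 5 prime ratio were chosen after seeing the data.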

Results

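Whole-lung gene expression was compared between AJ mice, which the labels call hyperresponsive, and C3H mice, 6 h and 24 h after aspiration of allergen or of PBS alone. Each of the 8 groups held 5 arrays. The design addresses which genes respond to allergen, how the response differs between strains and between times, and how the strains and times differ without allergen. Values are log2(intensity + 16), and adjusted p-values are from limma unless another test is named. The number of arrays limits the precision.

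In AJ mice at 6 h after allergen, Clca1, a secreted goblet cell protein, had the largest change, a log2 fold change of 6.64 ± 0.55 (SE, adjusted p = 8.63e-12). Its log2 level was 5.44 ± 1.11 in PBS mice and 12.08 ± 0.09 with allergen (SD, n = 5). Itln1, a lectin of goblet cells, rose by 5.17 ± 0.26 and Chil4, a chitinase-like protein, by 4.32 ± 0.30. S100a8 and S100a9, which form the neutrophil protein calprotectin, rose by 3.97 ± 0.46 and 3.94 ± 0.50, and Acod1, the enzyme that makes itaconate, by 3.92 ± 0.32. The largest falls were in the heat shock gene Hspa1b (-2.95 ± 0.23), the transcription factor Meis1 (-2.53 ± 0.24) and Hspa1a (-2.33 ± 0.25), which is near-identical in sequence to Hspa1b. The rank of Meis1 depends on the pseudocount: it was -3.87 with 1 and -1.39 with 64, beside -3.01 and -2.76 for Hspa1b. The endothelial transcription factor Sox18 stood at -2.29 ± 0.18 and the Notch target Hey1 at -2.23 ± 0.14.

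Of 26 measured chemokines, 18 rose and 0 fell in AJ mice at 6 h (19 rose adjusted over the list alone; camera adjusted p = 5.88e-31). Cxcl5 (3.79 ± 0.32), Ccl3 (3.56 ± 0.28) and Cxcl2 (3.53 ± 0.25), ligands that attract leukocytes, led the list. In the type 2 list, 22 of 28 members rose and 1 fell, the same counts as adjusted over the list alone. These included Ccl24 (3.40 ± 0.31) and Ccl11 (3.17 ± 0.27), the eotaxins. The type 2 cytokines Il4, Il13 and Il5 rose by 1.25 ± 0.17, 1.19 ± 0.21 and 0.68 ± 0.19 (adjusted p = 6.08e-07, 3.55e-05 and 0.00661). These sizes depend on the pseudocount, at 1.55, 2.47 and 1.71 with 1 and 0.79, 0.49 and 0.25 with 64. In the mucus list 13 of 22 rose and 1 fell, again as adjusted over the list alone. Tff2 (3.10 ± 0.41), Slc26a4 (3.03 ± 0.33) and the mucin Muc5ac (2.98 ± 0.32) came behind Clca1 and Itln1. Of 35 acute phase and innate inflammation genes, 26 rose (28 adjusted over the list alone), including Socs3 (2.88 ± 0.17) and Il6 (2.78 ± 0.21). Of 28 interferon response genes, 24 rose (24 adjusted over the list alone), including Cxcl10 (3.37 ± 0.22) and Mx2 (2.14 ± 0.25). Among 17 neutrophil markers 14 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone. Of 20 innate sensors 8 rose (10 adjusted over the list alone), led by Trem1 (2.51 ± 0.18) and Cd14 (2.43 ± 0.19).

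Other lists were called in AJ mice at 6 h as well. Complement had 8 of 20 members higher (9 adjusted over the list alone), among them Cfp (1.81 ± 0.30). Class II presentation had 6 of 12 higher (8 adjusted over the list alone), among them H2-Eb1 (0.82 ± 0.14). The macrophage list had 11 of 23 higher (14 higher and 1 lower adjusted over the list alone), with the scavenger receptor Msr1 at 1.10 ± 0.18. In the extracellular matrix list 11 of 29 rose and 3 fell (14 and 3 adjusted over the list alone). Thbs1, encoding thrombospondin, rose by 2.13 ± 0.13, and the crosslinking enzyme Lox changed by -0.77 ± 0.25. In the glucocorticoid and stress list 9 of 20 rose and 3 fell (10 and 3 adjusted over the list alone). The metallothioneins Mt2 and Mt1 rose by 1.48 ± 0.19 and 1.45 ± 0.18. Markers of T and NK cells rose in 8 of 24 members (9 adjusted over the list alone; adjusted p = 0.0813 with an estimated correlation), led by Cd3d (2.64 ± 0.39). B and plasma cell markers rose in 7 of 15 (7 adjusted over the list alone; adjusted p = 0.0928 with an estimated correlation), led by Jchain (2.51 ± 0.46). Alveolar epithelium markers fell in 5 of 14 (5 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), among them the water channel Aqp5 (-0.81 ± 0.16). The other 12 calls held with an estimated correlation, that of the glucocorticoid and stress list not without PBS replicate 3 (adjusted p = 0.0552).

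The remaining 12 lists were not called in AJ mice at 6 h. Of 16 clock genes 4 rose and 7 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.475). Nfil3, a transcriptional repressor, rose by 1.88 ± 0.18. Dbp, Tef and Hlf, related clock-output transcription factors, changed by -1.79 ± 0.21, -1.55 ± 0.12 and -1.36 ± 0.14. In the oxidative stress list 2 of 23 rose and 10 fell (5 and 11 adjusted over the list alone), with haem oxygenase Hmox1 at -1.68 ± 0.25. Endothelium markers fell in 5 of 18 (6 adjusted over the list alone), among them Ramp2 (-1.07 ± 0.15). Erythroid markers fell in 3 of 8 (3 adjusted over the list alone), among them Alas2 (-0.76 ± 0.26). In the mast cell and basophil list 2 of 13 rose and 1 fell (2 and 1 adjusted over the list alone). The rises were the basophil protease Mcpt8 (1.76 ± 0.24) and Hdc (1.72 ± 0.27). Club cell markers had 2 of 14 higher and 2 lower (3 and 3 adjusted over the list alone). Smooth muscle markers had 2 of 13 lower (2 adjusted over the list alone) and ciliated cell markers 1 of 11 lower (0 adjusted over the list alone). The cell cycle list had 3 of 32 higher and 1 lower (2 and 1 adjusted over the list alone). None of 7 eosinophil, 21 cardiac and skeletal muscle or 10 adipose markers passed, nor did any adjusted over the list alone. The eosinophil markers were dim, with a mean log2 level of 5.08 with PBS and 5.20 with allergen. Their intensities lay near the pseudocount, so this result says little about eosinophil transcripts. The median and mean differed in sign in the cell cycle list (-0.03 and 0.04). In the ciliated list the test and the median of 0.01 pointed up, against a mean of -0.03. In total 2358 of 12393 genes changed in AJ mice at 6 h, 871 higher and 1487 lower (36.9% higher). With arrays centred on their medians 1106 were higher and 974 lower (53.2%).

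**Figure D1:**
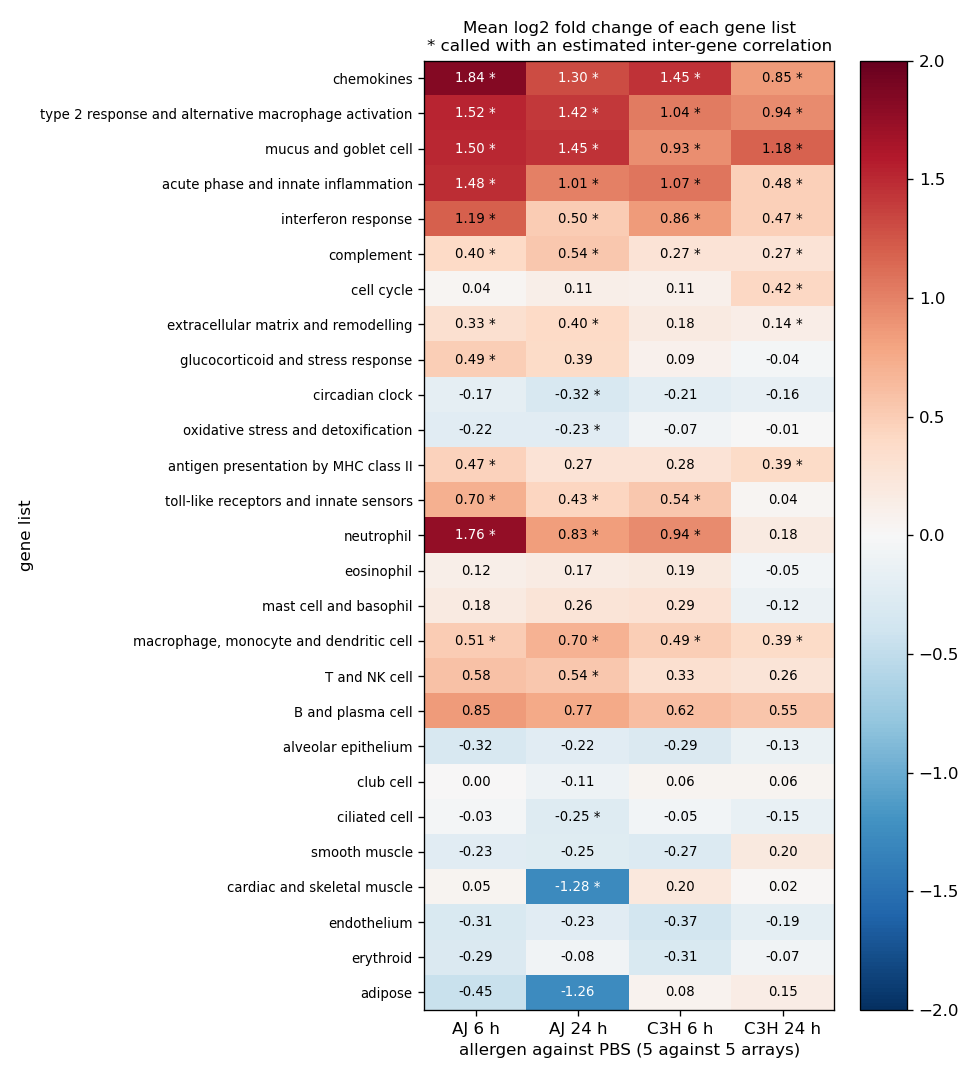
Mean log2 fold change over the members of each of the 27 gene lists (vertical axis) for allergen against PBS in the 4 groups of strain and time (horizontal axis), with 5 arrays against 5 and a star marking lists called with an estimated correlation. Chemokines averaged 1.84 in AJ mice at 6 h and 0.85 in C3H mice at 24 h, and the cardiac and skeletal muscle list averaged -1.28 in AJ mice at 24 h.

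In AJ mice at 24 h, Clca1 again rose with allergen, by 6.60 ± 0.55, as did Itln1 by 4.80 ± 0.26 and Muc5ac by 2.74 ± 0.32 (adjusted p = 2.85e-11, 5.14e-16 and 7e-08). Rnase2a, a ribonuclease of the eosinophil-associated family, rose by 5.11 ± 0.30, Chil4 by 4.83 ± 0.30 and Arg1, an arginase of alternatively activated macrophages, by 4.27 ± 0.34. Saa3, an acute phase protein, rose by 4.0 ± 0.38 and the anion exchanger Slc26a4 by 3.71 ± 0.33. Thrsp, a gene of lipid synthesis in the adipose list, stood at -2.92 ± 0.74. Among genes whose groups did not overlap, the largest falls were in Dbp (-2.48 ± 0.21), Reep6 (-2.42 ± 0.27) and Pgam2, a muscle glycolytic enzyme (-2.22 ± 0.47). Nr1d1, a repressor of the clock, stood at -2.01 ± 0.22. The cytokine genes Il4, Il5 and Il13 did not pass, at 0.23 ± 0.17, -0.02 ± 0.19 and 0.58 ± 0.21.

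Macrophage markers rose in 15 of 23 members and fell in 1 in AJ mice at 24 h (16 and 1 adjusted over the list alone; camera adjusted p = 9.69e-17). The scavenger receptor Cd163 (2.65 ± 0.20), the mannose receptor Mrc1 (1.79 ± 0.17) and the protease Ctsk (1.63 ± 0.20) led the list. Chemokines rose in 17 of 26 (20 higher and 1 lower adjusted over the list alone), now led by Ccl8 (3.45 ± 0.20) and Ccl24 (3.43 ± 0.31). The type 2 list had 15 of 28 higher (19 higher and 1 lower adjusted over the list alone) and the mucus list 13 of 22 higher and 1 lower (15 and 1 adjusted over the list alone). The acute phase list had 20 of 35 higher (25 adjusted over the list alone). Interferon response genes rose in 10 of 28 (16 adjusted over the list alone), with Irf7 at 1.10 ± 0.18. Complement genes rose in 8 of 20 (9 adjusted over the list alone), with Cfb at 2.16 ± 0.21. Neutrophil markers rose in 7 of 17 (8 higher and 1 lower adjusted over the list alone) and innate sensors in 6 of 20 (12 adjusted over the list alone). T and NK cell markers rose in 7 of 24 (12 adjusted over the list alone), with Cd3d at 1.90 ± 0.39. Allergen replicate 3 lay apart in that list (mean level 6.78, others 5.99 to 6.14), and without it the list had adjusted p = 0.0706 with an estimated correlation. Without PBS replicate 1 or 5 the T and NK list had 0.0537 or 0.0504, and without allergen replicate 5 the neutrophil list had 0.0518. In the extracellular matrix list 13 of 29 rose and 3 fell (14 and 6 adjusted over the list alone). Timp1, a metalloproteinase inhibitor, rose by 2.98 ± 0.20 and the collagen gene Col5a2 by 0.99 ± 0.12.

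The clock list was called in AJ mice at 24 h, with 4 of 16 genes higher and 5 lower (4 and 6 adjusted over the list alone; adjusted p = 0.0152). The call was lost with camera on ranks (adjusted p = 0.23). Nr1d2 fell by 1.32 ± 0.21 and Arntl, the positive regulator that Nr1d1 represses, rose by 0.90 ± 0.15. In the oxidative stress list 2 of 23 rose and 7 fell (3 and 8 adjusted over the list alone; adjusted p = 0.000768). The epoxide hydrolase Ephx1 stood at -1.14 ± 0.12 and Hmox1 at 0.99 ± 0.25. Ciliated cell markers fell in 1 of 11 (1 adjusted over the list alone; adjusted p = 0.0144), the microtubule gene Tppp3 (-0.76 ± 0.14). With an estimated correlation that call was lost without PBS replicate 1, 4 or 5 or allergen replicate 3 (adjusted p = 0.0537, 0.0566, 0.0733 and 0.0634). Cardiac and skeletal muscle markers fell in 7 of 21 (16 adjusted over the list alone; adjusted p = 2.19e-11). Among them were the cardiac genes Tnni3 (-1.59 ± 0.34) and Myl7 (-1.42 ± 0.31). The mean of that list was 7.51 ± 0.33 with allergen and 8.79 ± 0.32 with PBS (SD, n = 5), a difference of -1.28. The exact permutation p was 0.00794, the smallest that 5 against 5 can give, and 0.254 after adjustment over the tests of its family. With an estimated correlation the muscle call was lost without PBS replicate 1, 3 or 5 (adjusted p = 0.0567, 0.0554 and 0.0733) or allergen replicate 3 or 5 (0.057 and 0.0703). Adipose markers fell in 2 of 10 (3 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation), with the lipid droplet gene Cidec at -1.14 ± 0.35.

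Other calls in AJ mice at 24 h were lost with an estimated correlation. Stress response had 5 of 20 higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0825 with an estimated correlation). Class II presentation had 2 of 12 higher (5 adjusted over the list alone; adjusted p = 0.0683 with an estimated correlation). B and plasma cell markers had 6 of 15 higher, with Jchain at 2.03 ± 0.46 (8 adjusted over the list alone; adjusted p = 0.0683 with an estimated correlation). The mast cell list (1 of 13 higher, 1 adjusted over the list alone; adjusted p = 0.0983 with an estimated correlation) had Mcpt8 at 1.52 ± 0.24. Alveolar epithelium had 2 of 14 lower (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Club cell markers had 5 of 14 lower (5 adjusted over the list alone; adjusted p = 0.156 with an estimated correlation). Smooth muscle had 1 of 13 lower (2 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation). Endothelium had 1 of 18 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.168 with an estimated correlation). Cell cycle, eosinophil and erythroid lists were not called. The eosinophil list was again dim, at a mean log2 level of 5.11 with PBS and 5.28 with allergen. In all 971 genes changed, 565 higher and 406 lower. With muscle and adipose list means as covariates, chosen after seeing the data, 572 genes passed.

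**Figure D2:**
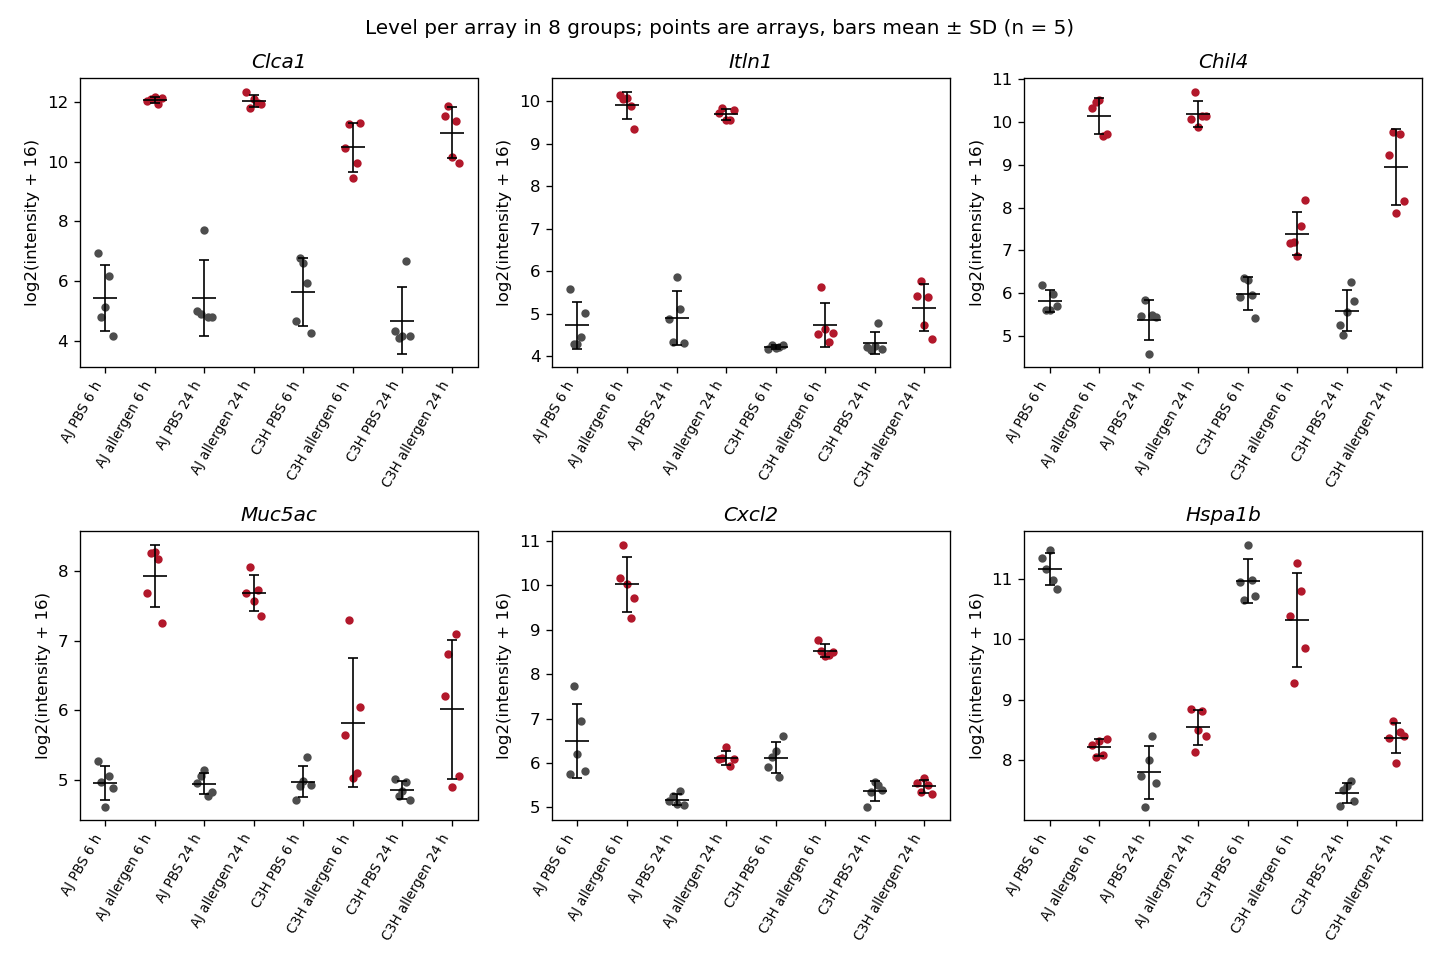
Log2(intensity + 16) of 6 genes on each array (points, grey for PBS and red for allergen) in the 8 groups, with bars for the mean ± SD (n = 5). Itln1 lay between 9.34 and 10.14 in AJ mice 6 h after allergen and between 4.33 and 5.63 in C3H mice, and Hspa1b lay between 10.83 and 11.47 in AJ mice 6 h after PBS.

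In C3H mice at 6 h, Clca1 rose by 4.85 ± 0.55 (adjusted p = 6.75e-08), from 5.64 ± 1.14 to 10.49 ± 0.81 (SD, n = 5). Ccl24 rose by 3.70 ± 0.31, Cxcl5 by 3.26 ± 0.32 and Cxcl1 by 3.08 ± 0.33. Saa3 rose by 2.94 ± 0.38 and Aldh1a3, which makes retinoic acid, by 2.46 ± 0.19. Il4, Il13 and Il5 rose by 0.75 ± 0.17, 0.72 ± 0.21 and 0.64 ± 0.19 (adjusted p = 0.00372, 0.0243 and 0.0248), while Muc5ac did not pass (0.85 ± 0.32). The cytokine values were 1.03, 1.62 and 1.34 with a pseudocount of 1, where Il5 did not pass (adjusted p = 0.106), and 0.41, 0.28 and 0.25 with 64. Falls included Pnkd (-1.15 ± 0.25), the transcription factor Etv5 (-1.14 ± 0.19) and the clock gene Per1 (-1.14 ± 0.21).

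Chemokines rose in 18 of 26 members in C3H mice at 6 h (19 adjusted over the list alone; camera adjusted p = 3.05e-31). Type 2 genes rose in 21 of 28 (21 adjusted over the list alone), including the alarmin Il33 (1.74 ± 0.19). The mucus list had 11 of 22 higher (13 adjusted over the list alone), with the immunoglobulin transporter Pigr at 2.07 ± 0.30. The acute phase list had 25 of 35 higher (28 adjusted over the list alone), with Il1b at 2.01 ± 0.24 and Tnf at 1.90 ± 0.26. Interferon response genes rose in 14 of 28 (16 adjusted over the list alone), among them Cxcl10 (2.68 ± 0.22) and the interferon-induced GTPase Iigp1 (2.24 ± 0.20). Neutrophil markers rose in 10 of 17 (11 adjusted over the list alone) and innate sensors in 7 of 20 (11 adjusted over the list alone). Macrophage markers rose in 10 of 23 (11 adjusted over the list alone) and complement genes in 3 of 20 (3 adjusted over the list alone). With an estimated correlation the complement call was lost without PBS replicate 2 or 3 (adjusted p = 0.0663 and 0.0667) or allergen replicate 1, 2 or 3 (0.0623, 0.075 and 0.0528). The dendritic cell lectin Cd209a rose by 1.63 ± 0.11.

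A further 10 lists were called in C3H mice at 6 h and lost with an estimated correlation. Endothelium fell in 5 of 18 (8 adjusted over the list alone; adjusted p = 0.0551 with an estimated correlation), with the angiopoietin receptor Tek at -0.61 ± 0.12. Alveolar epithelium fell in 3 of 14 (4 adjusted over the list alone; adjusted p = 0.0551 with an estimated correlation). The clock list had 3 of 16 higher and 5 lower (4 and 6 adjusted over the list alone; adjusted p = 0.0551 with an estimated correlation), with Dbp at -1.08 ± 0.21. Smooth muscle had 1 of 13 lower and erythroid markers 0 of 8 (4 and 0 adjusted over the list alone; adjusted p = 0.293 and 0.154 with an estimated correlation). Extracellular matrix had 5 of 29 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation). Class II presentation had 1 of 12 and mast cells and basophils 1 of 13 higher (2 and 1 adjusted over the list alone; adjusted p = 0.0914 and 0.0551 with an estimated correlation). T and NK cells had 2 of 24 and B and plasma cells 3 of 15 higher (2 and 6 adjusted over the list alone; adjusted p = 0.153 and 0.107 with an estimated correlation). The remaining 8 lists were not called. Among them the muscle list pointed down in the test against a mean of 0.20, as did the club cell list against a mean of 0.06. In all 944 genes changed, 487 higher and 457 lower, and 370 passed when the 2 groups were fitted alone. Without allergen replicate 1, 362 were higher and 295 lower.

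In C3H mice at 24 h, Clca1 was again highest, at a log2 fold change of 6.30 ± 0.55 (adjusted p = 4.36e-10). Rnase2a rose by 4.09 ± 0.30, Chil4 by 3.36 ± 0.30, Slc26a4 by 3.30 ± 0.33, Ccl24 by 3.16 ± 0.31 and the acidic chitinase Chia1 by 2.29 ± 0.20. Muc5ac rose by 1.16 ± 0.32, from 4.86 ± 0.13 to 6.01 ± 1.0 (SD, n = 5). The rise was uneven: allergen replicates 3 and 5, at 4.90 and 5.06, lay in or near the PBS range of 4.70 to 5.01. Il4, Il5 and Il13 did not pass (0.06 ± 0.17, 0.22 ± 0.19 and 0.48 ± 0.21). Rassf1, a Ras-association gene, had the largest fall (-2.05 ± 0.28). Other falls were in Sprr1a, a gene of the cornified envelope (-1.12 ± 0.24), the endothelial proteoglycan Esm1 (-1.07 ± 0.24) and the tight junction gene Cldn4 (-1.04 ± 0.20).

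Proliferation genes rose in C3H mice at 24 h, with 8 of 32 cell cycle members higher (19 adjusted over the list alone; camera adjusted p = 3.75e-14). They included Mki67 (0.99 ± 0.25) and Birc5 (0.80 ± 0.20). The mucus list had 12 of 22 higher (13 higher and 1 lower adjusted over the list alone), including Tff2 (2.63 ± 0.41) and Agr2 (2.21 ± 0.35). The type 2 list had 11 of 28 higher (19 higher and 2 lower adjusted over the list alone), including Arg1 (2.38 ± 0.34). Chemokines had 12 of 26 higher and 1 lower (15 and 1 adjusted over the list alone). Interferon response had 8 of 28 higher (11 adjusted over the list alone) and acute phase 9 of 35 (12 adjusted over the list alone). Class II presentation rose in 5 of 12 (9 higher and 1 lower adjusted over the list alone), with the invariant chain Cd74 at 0.59 ± 0.12. Macrophage markers rose in 9 of 23 (11 higher and 1 lower adjusted over the list alone). Complement had 5 of 20 higher (6 adjusted over the list alone) and extracellular matrix 6 of 29 (6 higher and 1 lower adjusted over the list alone). The extracellular matrix call was lost with quantile normalization (adjusted p = 0.128) and with camera on ranks (adjusted p = 0.114).

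Another 4 lists were called in C3H mice at 24 h and lost with an estimated correlation. T and NK cells had 3 of 24 and B and plasma cells 1 of 15 higher (5 and 6 adjusted over the list alone; adjusted p = 0.278 and 0.115 with an estimated correlation). Smooth muscle had 0 of 13 passing (0 adjusted over the list alone; adjusted p = 0.424 with an estimated correlation). Endothelium had 1 of 18 higher and 1 lower (1 and 2 adjusted over the list alone; adjusted p = 0.424 with an estimated correlation). Neutrophil markers and innate sensors were not called, with 1 of 17 and 0 of 20 higher (2 higher and 1 lower, and 0, adjusted over the list alone). Among other lists without a call, the median and mean differed in sign for club cell (-0.01 and 0.06), muscle (-0.08 and 0.02), erythroid (0.03 and -0.07) and adipose (-0.12 and 0.15). The stress list pointed up in the test against a mean of -0.04. In all 402 genes changed, 260 higher and 142 lower. The count moved with single arrays: without PBS replicate 1, 3, 4 or 5 it was 245, 232, 260 or 238. Without allergen replicate 1, 2 or 4 it was 194, 188 or 620. It was 161 with the 2 groups fitted alone and 714 with array weights.

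Many of the called genes were shared by both strains. At 6 h, 345 genes were higher in both and 274 lower in both, against 34.2 and 54.8 expected from independent lists. Another 7 changed in opposite directions. At 24 h, 158 were higher and 23 lower in both (11.9 and 4.65 expected), and 1 was opposite. Across genes, which are not independent replicates, the fold changes of the strains correlated at a Pearson r of 0.612 at 6 h and 0.452 at 24 h (Spearman 0.439 and 0.244). Among genes called in the same direction, the change was larger in AJ for 459 of 619 (74.2%) at 6 h and 131 of 181 (72.4%) at 24 h. These shares were not computed with arrays centred on their medians, which gave 974 falls in place of 1487 in AJ at 6 h. A part played by scaling was therefore not tested. Each strain had its own PBS arrays. Between 6 h and 24 h, AJ mice shared 343 higher and 135 lower genes (39.7 and 48.7 expected), with 19 opposite, and C3H mice shared 110 and 22 (10.2 and 5.24 expected), with 0 opposite.

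**Figure D3:**
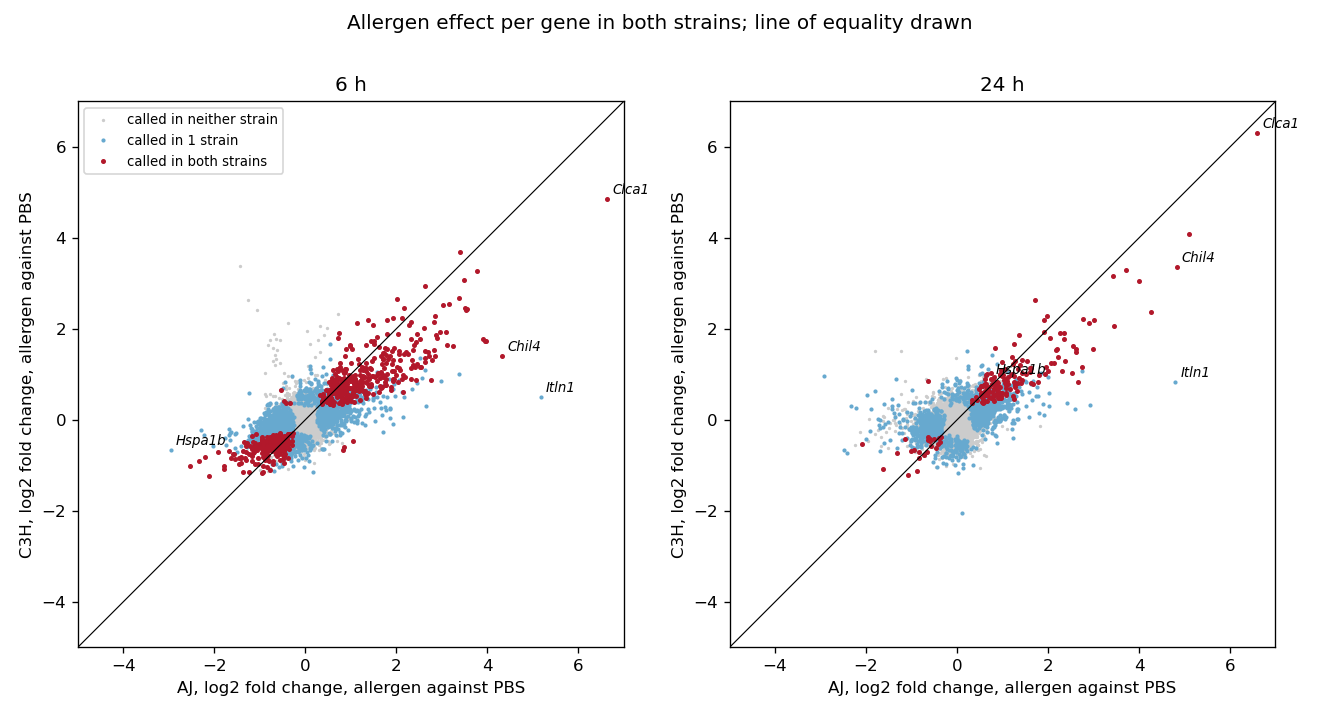
Log2 fold change of each of 12393 genes for allergen against PBS in C3H mice (vertical axis) against AJ mice (horizontal axis), at 6 h and 24 h, with colours for genes called in neither, 1 or both strains and a line of equality. Clca1 lies at 6.64 and 4.85 at 6 h, while Itln1 lies at 5.17 in AJ and is not called in C3H.

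The difference of the allergen effect between strains at 6 h was tested directly, as C3H minus AJ. Itln1 differed most, at -4.66 ± 0.37 (adjusted p = 7.49e-11): its log2 level went from 4.73 ± 0.56 to 9.90 ± 0.33 in AJ and from 4.22 ± 0.04 to 4.73 ± 0.51 in C3H (SD, n = 5). Chil4 (-2.92 ± 0.42), the neutrophil growth factor gene Csf3 (-2.36 ± 0.50), Acod1 (-2.15 ± 0.45), Muc5ac (-2.13 ± 0.45) and Mx2 (-2.07 ± 0.35) also responded less in C3H. Hspa1b (2.29 ± 0.33), Sox18 (2.06 ± 0.26), Hey1 (1.89 ± 0.20) and Meis1 (1.51 ± 0.34), which fell in AJ, had a positive difference. Clca1 and Ccl11 were not shown to differ (-1.79 ± 0.78 and -0.62 ± 0.39; adjusted p = 0.268 and 0.512).

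Of 28 interferon response genes, 8 had a smaller effect in C3H at 6 h (3 larger and 10 smaller adjusted over the list alone; camera adjusted p = 2.77e-06). The list had adjusted p = 0.0971 with an estimated correlation. Its members included Oasl1 (-1.59 ± 0.23) and Mx1 (-1.55 ± 0.22). The neutrophil list had 4 of 17 smaller (1 larger and 8 smaller adjusted over the list alone; adjusted p = 0.066 with an estimated correlation), with the granule genes Ngp (-1.52 ± 0.30) and Camp (-1.42 ± 0.33). Acute phase genes had smaller effects in 6 of 35, with Il6 at -1.90 ± 0.30 (1 larger and 11 smaller adjusted over the list alone; adjusted p = 0.0945 with an estimated correlation). Chemokines had 4 of 26 smaller (1 larger and 8 smaller adjusted over the list alone; adjusted p = 0.0945 with an estimated correlation). Type 2 genes had 3 of 28 and mucus genes 3 of 22 smaller (1 larger and 7 smaller, and 4 smaller, adjusted over the list alone; adjusted p = 0.066 and 0.145 with an estimated correlation). In the stress list 1 of 20 was larger and 5 smaller (1 and 8 adjusted over the list alone; adjusted p = 0.066 with an estimated correlation). None of the 11 list calls at 6 h held with an estimated correlation. In all 267 genes differed, 142 positive and 125 negative (53.2% positive). With arrays centred on their medians 79 and 149 differed (34.6%). With the 4 groups fitted alone the count was 112, and with array weights 478. Without AJ allergen replicate 1, 238 were positive and 153 negative (60.9%).

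At 24 h Itln1 again differed most between strains in its response to allergen, at -3.97 ± 0.37 (adjusted p = 8.13e-09). Its mean intensity in C3H was again low, at 4.18 with PBS and 21.4 with allergen, and probe sequence was not tested. Rassf1 (-2.15 ± 0.40), the Schlafen gene Slfn4 (-2.05 ± 0.44) and Cd163 (-1.82 ± 0.29) also had a negative difference. The airway secretory protein gene Bpifa1 (2.52 ± 0.58), the biliverdin reductase Blvrb (2.25 ± 0.49), Dbp (1.82 ± 0.30) and Nr1d1 (1.58 ± 0.31) had a positive one. Among the clock genes Arntl differed too, at -0.92 ± 0.21. Acute phase genes were led by Timp1 (-1.42 ± 0.28; 1 of 35 smaller, 11 adjusted over the list alone; list adjusted p = 0.0857 with an estimated correlation). The muscle list was called with a positive difference (0 of 21, 8 adjusted over the list alone; adjusted p = 5.42e-11, and adjusted p = 0.0986 with an estimated correlation). None of the 17 list calls held with an estimated correlation. In all 57 genes differed, 28 positive and 29 negative (49.1% positive). With arrays centred on their medians 32 and 18 differed (64%), and with the 4 groups fitted alone 16 and 33 (32.7%). With muscle and adipose covariates 6 genes passed, and with array weights 200. Without single arrays the count was 34 or 20 (AJ PBS replicate 1 or 5), or 28, 23 or 37 (AJ allergen 1, 2 or 5). It was 25, 30, 36 or 31 (C3H PBS 1, 3, 4 or 5) and 19, 30, 177 or 34 (C3H allergen 1, 3, 4 or 5).

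Among PBS mice, several of the largest strain differences stood at both times. H2-D1, an MHC class I gene whose sequence varies between inbred strains, was lower in C3H, at -3.11 ± 0.13 at 6 h and -3.14 ± 0.13 at 24 h (adjusted p = 2.78e-19 and 1.84e-19). Pdxdc1 was higher in C3H by 2.97 ± 0.17 and 2.88 ± 0.17 by its brightest probe set. Another bright probe set of Pdxdc1 gave -2.29 and -2.60, and the mean of all its probe sets -0.16 and -0.39. The direction of its expression difference is therefore not settled. Mndal, an interferon-inducible gene, was higher by 2.74 ± 0.28 and 3.02 ± 0.28, and xanthine dehydrogenase, Xdh, was lower, at -1.77 ± 0.18 and -1.45 ± 0.18. Hc, which encodes complement C5 and is known to be defective in A/J mice, was higher in C3H by 1.59 ± 0.14 and 1.63 ± 0.14. Tlr4 was not shown to differ (0.25 ± 0.13 and 0.05 ± 0.13).

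Complement genes were higher in C3H PBS mice in 2 of 20 at 6 h (5 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation). They were higher in 3 of 20 at 24 h (3 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). Class II genes were higher in 2 of 12 at 6 h (4 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation), namely H2-Aa (0.51 ± 0.14) and H2-Eb1 (0.51 ± 0.14). At 24 h extracellular matrix genes were higher in 3 of 29 (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.000287, and 0.013 with an estimated correlation, or 0.0721 without AJ PBS replicate 4). Thbs1 stood at 0.79 ± 0.13 and Col5a2 at 0.64 ± 0.12. The adipose list was called lower (0 of 10, 1 adjusted over the list alone; adjusted p = 0.812 with an estimated correlation). The endothelial gene Vwf was higher at both times, by 1.12 ± 0.15 and 0.78 ± 0.15. In all 552 genes differed at 6 h (292 higher in C3H, 260 lower) and 239 at 24 h (135 and 104). At both times 76 were higher and 48 lower (3.18 and 2.18 expected), and 2 were opposite. At 6 h the Gapdh 3 prime over 5 prime log2 ratio was 0.18 ± 0.49 in AJ and -0.27 ± 0.17 in C3H PBS mice (SD, n = 5, exact permutation p = 0.0952 and 0.406 adjusted). With this ratio as a covariate, chosen after seeing the data, 239 genes passed. The 6 h count was 176 with the 2 groups fitted alone, 358 or 306 without AJ PBS replicate 2 or 3 and 356 without C3H PBS replicate 2. The 24 h count was 483 with array weights.

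In AJ mice the allergen effect was lower at 24 h than at 6 h for Acod1 (-3.11 ± 0.45), Csf3 (-2.79 ± 0.50), the pentraxin Ptx3 (-2.68 ± 0.22) and Cxcl10 (-2.54 ± 0.31; adjusted p = 1.2e-05, 0.000321, 4.39e-10 and 9.88e-07). Il4 also had a lower effect at 24 h (-1.02 ± 0.24), and the effects on Il13, Muc5ac and Clca1 were not shown to differ (-0.61 ± 0.29, -0.24 ± 0.45 and -0.04 ± 0.78). Cd163 (2.29 ± 0.29), Ccl8 (1.19 ± 0.28) and Cfb (1.59 ± 0.30) had a higher effect at 24 h. Hspa1b (3.69 ± 0.33), Hspa1a (2.99 ± 0.36) and Hmox1 (2.67 ± 0.36) had the largest positive differences. The Hspa1b log2 level at 6 h was 11.16 ± 0.26 with PBS and 8.21 ± 0.14 with allergen, and at 24 h 7.80 ± 0.44 and 8.54 ± 0.30 (SD, n = 5).

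Interferon response was the list whose difference between times in AJ held with an estimated correlation. In it 13 of 28 had a lower effect at 24 h (15 adjusted over the list alone; adjusted p = 4.73e-14, and 0.0203 with an estimated correlation). The other list calls were lost, and here too higher and lower refer to the effect at 24 h. Neutrophil markers were lower in 6 of 17 (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.0626 with an estimated correlation). Acute phase genes were higher in 2 of 35 and lower in 12 (4 and 15 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation). Chemokines were higher in 2 of 26 and lower in 7 (2 and 9 adjusted over the list alone; adjusted p = 0.167 with an estimated correlation). Innate sensors were lower in 4 of 20 and class II genes in 1 of 12 (4 and 1 adjusted over the list alone; adjusted p = 0.226 and 0.486 with an estimated correlation). Muscle markers were lower in 1 of 21 and adipose markers in 0 of 10 (1 and 0 adjusted over the list alone; adjusted p = 0.185 and 0.63 with an estimated correlation). In all 697 genes differed, 437 positive and 260 negative (62.7% positive). With arrays centred on their medians 274 and 337 differed (44.8%). With array weights 1118 genes passed.

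In C3H mice the allergen effect was lower at 24 h on the chemokine genes Cxcl2 (-2.30 ± 0.35), Ccl3 (-2.18 ± 0.40) and Cxcl1 (-2.06 ± 0.47; adjusted p = 0.000588, 0.00567 and 0.0257), as was that on Tnf (-1.88 ± 0.37). The effect was higher at 24 h on Chil4 (1.96 ± 0.42), Rnase2a (1.63 ± 0.42) and Hspa1b (1.56 ± 0.33). Acute phase genes had a lower effect in 7 of 35 (16 adjusted over the list alone; adjusted p = 0.0522 with an estimated correlation) and innate sensors in 4 of 20 (6 adjusted over the list alone; adjusted p = 0.0522 with an estimated correlation). The cell cycle list pointed up (0 of 32, 3 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation). None of the 10 list calls held with an estimated correlation. In all 109 genes differed, 54 positive and 55 negative, and 32 with the 4 groups fitted alone. Without single arrays the count was 53 or 56 (PBS 6 h replicate 1 or 2), or 50, 60 or 55 (PBS 24 h replicate 3, 4 or 5). It was 29 (allergen 6 h replicate 1) and 53 (allergen 24 h replicate 1). The positive count alone was 32 or 35 (PBS 6 h replicate 3 or PBS 24 h replicate 1) and 27 or 31 (allergen 6 h replicate 5 or allergen 24 h replicate 3).

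PBS mice differed between 6 h and 24 h as well. Hspa1b was lower at 24 h, at -3.36 ± 0.23 in AJ and -3.51 ± 0.23 in C3H (adjusted p = 1.59e-12 and 3.8e-13), and Hspa1a at -2.50 ± 0.25 and -3.15 ± 0.25. The chemokine Cxcl1 was lower, at -1.97 ± 0.33 and -1.80 ± 0.33, as were Hmox1 at -2.13 ± 0.25 and -1.71 ± 0.25 and the metallothionein Mt2 at -1.61 ± 0.19 and -1.72 ± 0.19. Gclc, an enzyme of glutathione synthesis, was lower at 24 h, at -1.63 ± 0.20 and -1.98 ± 0.20, and the thioredoxin reductase Txnrd1 at -1.29 ± 0.10 and -0.92 ± 0.10. Actn3 (2.24 ± 0.66) and Atp2a1 (1.72 ± 0.53), which encode an actinin and a calcium pump of skeletal muscle, were higher at 24 h in AJ.

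The glucocorticoid and stress list was lower at 24 h in 12 of 20 members in AJ PBS mice (15 adjusted over the list alone; camera adjusted p = 6.94e-18, and 0.000979 with an estimated correlation). In C3H 12 of 20 were lower (18 adjusted over the list alone; adjusted p = 1.44e-24, and 8.62e-05 with an estimated correlation). The glucocorticoid-induced gene Fkbp5 stood at -1.60 ± 0.21 in AJ and Atf3 at -1.98 ± 0.34 in C3H. The oxidative stress list had 5 of 23 lower in AJ (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.0768 with an estimated correlation). In C3H it had 1 of 23 higher and 4 lower (1 and 5 adjusted over the list alone; adjusted p = 0.0336 with an estimated correlation). Without PBS 6 h replicate 1, 2 or 3 that p was 0.0805, 0.101 or 0.055, and without PBS 24 h replicate 3 or 4 it was 0.143 or 0.0582. Ciliated cell markers were higher in 1 of 11 in AJ (5 adjusted over the list alone; adjusted p = 0.0116 with an estimated correlation), the radial spoke gene Rsph1 (0.81 ± 0.24). Muscle markers were higher in 1 of 21 in AJ (9 adjusted over the list alone; adjusted p = 0.464 with an estimated correlation), with list means of 7.83 ± 0.62 at 6 h and 8.79 ± 0.32 at 24 h (SD, n = 5). In AJ 666 genes differed, 359 higher and 307 lower (53.9% higher). With arrays centred on their medians 258 and 402 differed (39.1%). In C3H 398 differed, 218 and 180, and 43 were higher and 82 lower in both strains (6.32 and 4.46 expected). The AJ count was 268 with the Gapdh ratio and 267 with muscle and adipose means as covariates, 407 with the 2 groups fitted alone and 1149 with array weights. It was 342 or 350 without PBS 6 h replicate 2 or 3 and 412 without PBS 24 h replicate 2. Without PBS 24 h replicate 1 or 3, 228 or 237 were higher. The C3H count was 191 with the 2 groups fitted alone and 843 with array weights.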

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

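The splits of the arrays and the comparison of strain calls with AJ allergen calls were chosen before their results were seen. The tests of the clock and muscle patterns, the comparison of strain calls with C3H allergen calls and the test of opposite signs were chosen after. The prediction for opposite signs with the Gapdh ratio was written before its own result, with a covariate chosen after seeing the data.

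Arrays lying apart from the other 4 of their group came first. Among 336 groups of values, 20 had such an array, where chance alone gives about 1 in 20 groups, or 16.8. In AJ mice 24 h after allergen, replicate 5 had low list means for chemokines (7.55, others 7.82 to 7.88), type 2 genes (7.70, others 7.87 to 7.90) and muscle (6.94, others 7.57 to 7.77), and replicate 3 a high mean for T and NK cell markers (6.78, others 5.99 to 6.14). In AJ mice 6 h after allergen, replicate 3 was high for oxidative stress genes (8.99, others 8.83 to 8.87), replicate 5 low for Il13 (4.79, others 5.74 to 5.83) and replicate 1 high for the beta-actin 3 prime over 5 prime log2 ratio (0.94, others 0.19 to 0.30). In C3H mice given allergen, replicate 4 at 24 h was low for smooth muscle (8.16, others 8.51 to 8.56) and for cardiac and skeletal muscle (6.86, others 8.73 to 8.94), and replicate 2 at 6 h was high for Itln1 (5.63, others 4.33 to 4.63). In AJ PBS mice, replicate 4 at 6 h was high for ciliated cell markers (6.38, others 6.08 to 6.14), and at 24 h replicate 3 was low for endothelium (9.53, others 9.61 to 9.65) and high for Clca1 (7.70, others 4.79 to 5.0), while replicate 1 was low for Hc (7.80, others 8.40 to 8.52). In C3H PBS mice at 6 h, replicate 2 was low for acute phase genes (7.11, others 7.42 to 7.53) and high for erythroid markers (7.50, others 6.72 to 6.85). In C3H PBS mice at 24 h, replicate 5 was low for interferon genes (6.79, others 6.94 to 6.99), replicate 1 high for endothelium (9.90, others 9.62 to 9.68) and replicate 4 high for Clca1 (6.66, others 4.08 to 4.32) and Itln1 (4.77, others 4.16 to 4.25).

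The allergen effect differed between strains, by the test of the difference itself (limma, C3H minus AJ), in 267 genes at 6 h. The largest were Hspa1b 2.29, Sox18 2.06, Hey1 1.89, Zbtb16 1.82, Meis1 1.51 and Trmt1l 1.48, and on the negative side Itln1 -4.66, Chil4 -2.92, Csf3 -2.36, Acod1 -2.15, Muc5ac -2.13 and Mx2 -2.07. At 24 h it differed in 57 genes, with Bpifa1 2.52, Blvrb 2.25, Dbp 1.82, Reep6 1.69, Mettl27 1.64, Nr1d1 1.58, Itln1 -3.97, Rassf1 -2.15, Slfn4 -2.05, Cd163 -1.82, Gp2 -1.63 and Clec4e -1.53. Between times (24 h minus 6 h) it differed in AJ mice in 697 genes, with Hspa1b 3.69, Hspa1a 2.99, Hmox1 2.67, Cd163 2.29, Meis1 2.25, Lrr1 2.12, Acod1 -3.11, Csf3 -2.79, Ptx3 -2.68, Cxcl2 -2.59, Cxcl10 -2.54 and Zc3h12a -2.40. In C3H mice it differed in 109 genes, with Chil4 1.96, Rnase2a 1.63, Hspa1b 1.56, Vps45 1.34, Ccl12 1.32, Mlc1 1.14, Rassf1 -2.58, Cxcl2 -2.30, Ccl3 -2.18, Cxcl1 -2.06, Cxcl5 -2.0 and Tnf -1.88. The interferon response list differed between times in AJ mice (adjusted p = 0.0203 with an estimated correlation). Among 1555 probe sets without a gene name, which the comparisons leave out, the allergen effect passed in 131 and 52 in AJ mice at 6 h and 24 h, and in 40 and 24 in C3H mice.

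Other splits of the same arrays into groups of the same sizes were fitted, 100 for each contrast with the real one included. For allergen against PBS, 1 split, the real one, gave as many calls in each case: AJ at 6 h had 2358 against at most 604 in another split, AJ at 24 h 971 against 76, C3H at 6 h 944 against 426 and C3H at 24 h 402 against 94. The same held, with 1 split each, for strain in PBS mice (552 against 109 at 6 h, 239 against 11 at 24 h) and time in PBS mice (666 against 157 in AJ, 398 against 92 in C3H). For the difference between strains, 4 splits gave as many at 6 h (267, highest other 437) and 4 at 24 h (57, highest other 278), and for the difference between times 2 in AJ (697, highest other 961) and 2 in C3H (109, highest other 576). For the comparisons of 2 groups, a chance division of these arrays is argued against, at a share under 0.05. The splits exchange single arrays, and the labels do not say that each is a separate mouse. They therefore cannot exclude chance between mice, or another difference that follows the groups. In the splits of the differences, labels exchanged within a treatment let the strain or time difference itself enter, which is a structure of the samples. Such splits do not show what chance alone gives, so chance is not excluded for the differences. Whether that structure accounts for the splits that called several times the real count was not tested.

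Clock genes were displaced in AJ mice given allergen. Averaged over both times, Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per2 and Per3 had a median log2 fold change of -1.08 ± 0.21. Arntl, Npas2, Clock, Cry1 and Nfil3 had one of 0.69 ± 0.27. Taken at single times, the medians of these sets in AJ mice were -0.83 and 0.73 at 6 h and -0.79 and 0.72 at 24 h. In C3H mice the single-time medians were -0.63 and 0.46 at 6 h and -0.42 and -0.02 at 24 h. Errors in this paragraph are standard errors of the mean over the genes of a set, although they stand beside medians. The error of a difference combines those of its sets. These errors are not from limma and leave out the spread between arrays. Dilution of lung cells by entering leukocytes is argued against as the whole account of the lower set. The median of -1.08 lay -0.91 ± 0.21 from that of 70 markers of resident lung cells (-0.17 ± 0.04). This test was chosen after the pattern was seen, and a part played by dilution stays open. A different time of day of sampling cannot be told apart from an effect of the allergen on the clock: both could give the opposite medians of -1.08 and 0.69, the labels give no time of day, and PBS mice at 24 h against 6 h had medians of -0.24 and 0.01 in AJ and -0.21 and 0.26 in C3H. An effect of the allergen stays open.

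Strain differences in PBS mice may partly reflect sequence differences under the probes or, at 6 h, a difference in RNA quality. Of 53 strain calls at 24 h with a second bright probe set, 33 (62.3%) were borne out by it, against 126 of 162 (77.8%) for allergen calls in AJ at 24 h (Fisher's exact p = 0.031) and 36 of 67 (53.7%) for allergen calls in C3H (p = 0.36), and at 6 h 62 of 138 (44.9%) were (p = 6.03e-09 and 0.297). The second probe set had the opposite sign in 34 of 138 strain calls at 6 h, more than in 8 of 162 in AJ (Fisher's exact p = 1.23e-06) and 5 of 67 in C3H (p = 0.00392), and in 10 of 53 at 24 h (p = 0.00329 and 0.0935). With the Gapdh ratio as a covariate it had the opposite sign in 9 of 56 calls at 6 h (Fisher's exact p = 0.00402 against AJ and 0.14 against C3H), a smaller set. Probe sequence, RNA quality and expression cannot be told apart for these calls as a set, since the answer depends on the reference and, at 6 h, on the covariate, and a difference in expression between strains stays open.

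Muscle transcripts were lower in AJ mice 24 h after allergen, by a list mean of -1.28. A candidate explanation is muscle carried along with some lungs: the spread of this list between arrays of a group (median SD 0.49) exceeded that of 96.2% of the other lists, adipose being wider at 0.80. The list also differed by 0.97 between the AJ PBS groups (exact permutation p = 0.0159, 0.254 adjusted). Its SD reached 1.06 in AJ 6 h after allergen, against 0.33 and 0.32 in the AJ groups compared. In C3H 24 h after allergen the SD was 0.89, where replicate 4 lay apart (6.86, others 8.73 to 8.94). The change differed between strains by 1.30 (permutation p = 0.014). That test cannot decide whether an effect of allergen is shared by both strains. It was chosen after the fall in AJ was seen, and carried-along muscle could give such a difference too. An effect in AJ alone was not tested and stays open beside carried-along muscle, and with muscle and adipose covariates 572 genes passed in that comparison in place of 971, of which 527 were the same genes.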

How the results depend on the processing

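Over the named genes and the settings that refit the values, single arrays left out included and stricter thresholds not, 16145 values kept direction and side of the threshold, 1391 kept direction and lost the threshold, 11 gained it and 3 reversed. The filter on dim genes tested 610 of 690 named values. The 3 came from averaging all probe sets of a gene: Pdxdc1 between strains in PBS mice, -0.16 at 6 h and -0.39 at 24 h, and Angptl4 between times in AJ, -0.44. That these genes' probe sets differ in direction follows from the construction. Median centring, quantile normalization, pseudocounts of 1 and 64, the filter on the dimmest 25% of genes, trend and robust options and leaving out the arrays with the letter b moved no total count by more than 1.5 times. Counts by direction moved more. Median centring gave 974 lower in place of 1487 for AJ allergen at 6 h, 79 positive in place of 142 and 18 negative in place of 29 for the strain difference at 6 h and 24 h, and 274 positive in place of 437 for the time difference in AJ. A pseudocount of 1 gave 18 negative for the strain difference at 24 h and 34 positive in place of 54 for the time difference in C3H, and leaving out the letter b gave 33 there. For the same difference array weights gave 85 positive, and 84 were negative in place of 55 with the mean of all probe sets and 88 with muscle and adipose covariates. For the strain difference at 24 h the compared groups alone gave 16 positive in place of 28. The cause was not tested. The pseudocount set the size of dim genes. Of 317 named fold changes for allergen against PBS, 31 moved by more than 1.5 times with 1 and 82 with 64, and 0 changed sign. In AJ at 6 h Il13 was 2.47 and 0.49 with 1 and 64 against 1.19, Acod1 6.17 and 2.32 against 3.92, and Clca1 7.65 and 5.50 against 6.64. Without detection calls, signal over background was not measured, and changes of genes near the pseudocount are the least precise.

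The replicate block moved no count by more than 1.5 times and left the number of list calls for allergen against PBS at 72, where alone it was tested on lists. Replicate numbers did not pair the arrays: residuals of arrays with the same number correlated at 0.018 on average and with different numbers at -0.005, and 10 of 40 arrays matched their own number best.

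Stricter thresholds call fewer genes by construction. At an adjusted p under 0.01 the counts for allergen against PBS were 1529 and 533 in AJ (6 h and 24 h) and 467 and 136 in C3H, for the difference between strains 102 and 8, for strain in PBS mice 213 and 137, for the difference between times 341 in AJ and 12 in C3H, and for time in PBS mice 229 and 153. With an absolute log2 fold change of at least 1 they were, in the same order, 418, 224, 153, 73, 103, 32, 74, 48, 227, 47, 83 and 48. Fitting the compared groups alone uses fewer arrays and gave 370 and 161 for C3H allergen at 6 h and 24 h, 112 for the strain difference at 6 h, 176 for strain in PBS mice at 6 h, 32 for the time difference in C3H, and 407 in AJ and 191 in C3H for time in PBS mice. With array weights the counts were 714 for C3H allergen at 24 h, 478 and 200 for the strain difference, 483 for strain in PBS mice at 24 h, 1118 for the time difference in AJ, and 1149 and 843 for time in PBS mice; the cause was not tested. With muscle and adipose covariates, chosen after seeing the data, they were 572 for AJ allergen at 24 h, 6 for the strain difference at 24 h and 267 for time in AJ PBS mice. With the Gapdh ratio, also chosen after, they were 239 for strain in PBS mice at 6 h and 268 for time in AJ PBS mice; the cause was not tested. With an estimated correlation 46 of 72 list calls for allergen against PBS passed. The estimates exceed the preset for most lists, but whether this alone accounts for the lost calls was not tested. With camera on ranks 68 of the 72 were called. With the muscle and adipose covariates the muscle call in AJ at 24 h was lost (adjusted p = 0.547), which follows from the construction.

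Leaving out each array in turn gave 2067 to 2223 genes for AJ allergen at 6 h, 746 to 891 at 24 h, 657 to 1008 for C3H at 6 h and 188 to 620 at 24 h. The strain difference ranged from 196 to 391 at 6 h and 19 to 177 at 24 h, strain in PBS mice from 306 to 658 and 188 to 221, the time difference from 592 to 825 in AJ and 29 to 151 in C3H, and time in PBS mice from 342 to 790 in AJ and 285 to 403 in C3H. Of 52 list calls that held with an estimated correlation, 8 were lost so without some array, a setting chosen after seeing the data, and 0 at the preset. Of the 88 list calls lost with an estimated correlation, 22 were lost even at the preset without some array. The lowest C3H count at 24 h came without allergen replicate 2 and the highest without replicate 4, and the ends for the strain difference at 24 h came without C3H allergen replicate 1 and replicate 4. The cause was not tested.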

Other observations

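In AJ mice 6 h after allergen, Smad6, an inhibitor of BMP signalling, changed by -2.20 ± 0.22 (SE, n = 5 per group), the endothelial gene Tmem100 by -1.33 ± 0.23 and Kdr, the main VEGF receptor, by -0.63 ± 0.21 (limma adjusted p = 8.13e-10, 2.45e-05 and 0.0313). In C3H mice Tmem100 changed by -0.85 ± 0.23. The endothelium list, which holds Tmem100 and Kdr, was not called in AJ mice at 6 h (camera adjusted p = 0.0714). In the T and NK cell list, the inhibitory receptor Ctla4 rose by 2.33 ± 0.25 and the cytotoxic protease Gzmb by 2.18 ± 0.28 in AJ at 6 h, and the effect on both was smaller in C3H (-1.44 ± 0.35 and -1.68 ± 0.39). The call of that list in AJ mice at 6 h was lost with an estimated correlation (adjusted p = 0.0813). Kit, the stem cell factor receptor, changed by -0.79 ± 0.13 in AJ, and its effect differed between strains (0.90 ± 0.18).

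Reg3g, an antimicrobial lectin, rose at 6 h by 1.38 ± 0.46 in AJ and 2.19 ± 0.46 in C3H. Rtkn2, a marker of alveolar type I cells, changed by -1.30 ± 0.16 and -0.71 ± 0.16, and the cytochrome Cyp4b1 by -0.64 ± 0.11 and -0.47 ± 0.11. In PBS mice the secretory protein gene Bpifb1 was lower in C3H than in AJ (-0.59 ± 0.16 at 6 h and -0.77 ± 0.16 at 24 h).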
